A study of Mus musculus with 24 samples.

How the data were processed

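Gastrocnemius muscle of male B6D2F1 mice was profiled on Illumina bead arrays carrying 45281 probes. Per the labels' protocols, total RNA was extracted with the QIAGEN RNeasy mini kit and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The labels place the 24 arrays in 3 groups: young ad libitum (8 months), old ad libitum (24 months) and old caloric restricted (24 months). Names repeated in the labels were taken as repeated arrays of 1 mouse, which gave 6 young mice on 10 arrays, 6 old ad libitum mice on 7 arrays and 5 restricted mice on 7 arrays. Repeated arrays had a median correlation of 0.668 in their deviations from the mean of all arrays, against 0.0448 for different mice of a group. The labels do not say that the names stand for separate animals in so many words, so the p-values measure the spread between these samples. The feeding state and time of day at sampling are not given in the sources used here.

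The deposited non-normalized table holds, per the file headers, an average signal intensity per probe and array, and a detection p-value per probe and array. Per the submitters' processing notes the values came from GenomeStudio, with no version or normalization given in the sources used here. The authors' series matrix holds intensity values on a linear scale, whose columns had medians between 98.6 and 98.7 and correlated with the signals of the same array at 0.999 or more on the log2 scale, so they were treated as quantile normalized, and they served as an alternative. Median signals per array ran from 82.9 to 119.7. The number of arrays limits the precision.

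Signals were background corrected and quantile normalized with neqc (limma 3.58.1 in R 4.3.3, offset 16), which infers the negative control distribution from the detection p-values. Probes detected (detection p under 0.01) on at least 5 arrays were kept, 15268 in all. A probe was named where the platform annotation gave 1 gene symbol: 34885 probes had 1, 18 had several and 10378 were not listed. Symbols of 34807 probes were checked through the entrez identifier, and none changed. Of the kept probes 2003 had no single symbol and were not tested. Arrays of a mouse were averaged, and of the probes of a gene the one with the highest mean was used, which left 8943 genes, of which 3069 had more than 1 kept probe. A gene not detected on any array of a group has only a bound there. Its fold was taken as the other group's mean over the mean of, per array, the higher of the lowest detected signal and the probe's own value.

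Group means were compared with limma (lmFit and eBayes, 1 fit over 17 mice, adjusted p by Benjamini-Hochberg, threshold 0.05, two-sided). The chosen lists were 26 pathway lists and 9 lists of cell type markers, and 934 of their 935 entries were resolved to a symbol. Each was tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists and comparisons together. With an estimated correlation no list passed. The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named were the 10 largest rises and 10 largest falls past the threshold in each comparison (5 and 5 for restricted against young), clone and locus names left out, up to 4 members of each list with the smallest p with age or under restriction, and 15 genes of mitochondrial and stress biology. In the text up to 4 members were named for lists that passed with age or under restriction and fewer for the others.

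The procedure was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 8943 genes. For age 67% and 94% of these were recovered, for restriction 57% and 93%, and for restricted against young 64% and 94%. The simulated genes varied independently of each other and with the same spread in every group, unlike the real genes, so these shares may not hold for the real data. Alternatives were no background correction, scaling to the 75th percentile, the authors' values, no or a stricter detection filter, 24 arrays with or without the chip as a block, 1 array per mouse, all probes or their mean, a replicate block, a trend and robust prior, array weights, fits on the 2 groups compared, an estimated correlation, fry, and leaving out each mouse. Another 4 alternatives were chosen after seeing the data: the slow fibre score or the adipocyte score as a covariate, and leaving out old ad libitum mice 5 and 6 or young mice 1, 2 and 3, which were picked by their values. The 4 chips each held 6 arrays of all 3 groups. Figures were drawn with matplotlib 3.10.9.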

Results

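Gene expression was measured in gastrocnemius muscle, a calf muscle made mostly of fast fibres, of male B6D2F1 mice, a hybrid strain. The 3 groups were young mice fed ad libitum, aged 8 months, old mice fed ad libitum, aged 24 months, and old mice of 24 months kept under caloric restriction, a reduced food intake. The study is about caloric restriction and muscle mitochondria in old age, so the genes of the mitochondrion are described on their own after the 3 comparisons. There were 6 young, 6 old ad libitum and 5 restricted mice on 24 Illumina bead arrays, and 5 of the mice were hybridised on more than 1 array. Between 13662 and 15176 of the 45281 probes were detected on an array of young mice, between 13974 and 14890 on an array of old ad libitum mice and between 13625 and 14401 on an array of restricted mice. After averaging the arrays of a mouse, 8943 genes were tested with limma. The number of mice limits the precision of every value, with a median SD between mice of a group of 0.18 on the log2 scale, against 0.09 between arrays of 1 mouse.

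Of 24 measured genes of denervation and the neuromuscular junction, 5 were higher in old ad libitum than in young mice past the threshold. Myh8, the perinatal myosin heavy chain, was 2.24-fold higher in old mice (log2 difference 1.16 ± 0.19 SE, adjusted p = 0.00542), with all 6 old mice above all 6 young mice. Other probes of Myh8 had smaller log2 differences, of 0.83 (p = 4.8e-05) and 0.52 (p = 0.000196). Chrnb1, a subunit of the acetylcholine receptor at the neuromuscular junction, was 1.41-fold higher (adjusted p = 0.013). Sln, encoding sarcolipin, a regulator of the calcium pump, was 5.03-fold higher, with an SD of 1.77 between old mice against 0.28 between young mice (adjusted p = 0.0467). In total 184 genes passed the threshold, of which 120 rose and 64 fell, and 16 changed more than 2-fold. Without young mice 1, 2 and 3, a choice made after their values were seen, 1 gene passed with age. All 184 kept their direction, with a median size of 0.42 against 0.46 and a median SE of 0.13 against 0.10. They were selected on data that include the mice kept, so the kept direction is no independent support. Leaving out the same 3 mice left 66 of the 284 genes of the diet comparison, whose fold changes involve no young mouse. The loss there comes from the shared estimate of the spread, with a median SE of 0.12 against 0.11. Young mice 1, 2 and 3 had array weights of 1.19, 2.33 and 1.71, against 0.44 to 1.26 in old ad libitum mice. A higher weight means a smaller spread, so most of the diet calls rest on the young mice in the fit. Without any young mouse 24 of the 284 passed. The smaller number of mice and the spread of those left out were not told apart. Among the largest rises were Rrad, a small GTPase (4.21-fold, adjusted p = 0.0239), and Cpne2, a calcium-dependent membrane-binding protein (3.09-fold, adjusted p = 0.00359). Rises were also found for Uchl1, a deubiquitinase abundant in neurons (2.31-fold, adjusted p = 0.0243), Slc23a3 (2.54-fold), Ttc9 (2.57-fold), Vmn1r65 (2.26-fold) and Slc1a3, a glutamate transporter (2.23-fold). In young mice Ttc9 had a log2 value of 6.23 in mouse 1 and at most 5.51 in the others. Uchl1 was at 5.31 in young mouse 2 and at 5.70 in the next lowest. The folds of Ttc9 and Uchl1 thus rest in part on values near background. Spock2 was not detected on any of the 10 arrays of young mice and was at least 1.77-fold higher in old mice. The largest falls were those of Htra4 (2.30-fold), Gpcpd1, a glycerophosphocholine phosphodiesterase (2.06-fold), and Amd2, of the polyamine pathway (1.89-fold). Falls of 1.62-fold to 1.69-fold were found for Abi3bp, an extracellular matrix protein, Auts2, Synm, the intermediate filament protein synemin, Cpeb1, Dlk1 and Nr3c1, the glucocorticoid receptor. A second probe of Abi3bp had a log2 difference of -0.18 (p = 0.149) against -0.76 for the probe used, and a second probe of Amd2 had -0.28 (p = 0.0623) against -0.92. Col4a4, a basement membrane collagen, was not detected in old ad libitum mice and was at least 1.03-fold higher in young mice (adjusted p = 0.00632).

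Of the 24 measured genes of denervation and the neuromuscular junction, 5 rose with age, none fell and 11 rose when adjusted over the list alone, with a median log2 difference of 0.39. Besides Myh8, Chrnb1 and Sln, these were Gadd45a, a stress-response gene (2.21-fold, adjusted p = 0.0396), and Myod1, a myogenic transcription factor named after its values were seen. The list passed camera with an adjusted p of 4.2e-07, while with an estimated correlation the adjusted p was 0.51. Its mean per mouse was 0.30 ± 0.34 (SD, n = 6) in old ad libitum mice, with the highest values in mice 5 and 6, and -0.27 ± 0.12 (SD, n = 6) in young mice. Of 33 genes of collagens and extracellular matrix, none passed over all genes tested, 16 fell and 1 rose when adjusted over the list alone, and 29 were lower in old mice, with a median of -0.35 (camera adjusted p = 4.7e-08, and adjusted p = 0.51 with an estimated correlation). The 15 fibroblast markers, of which 6 are also in the matrix list, had a median of -0.42 (camera adjusted p = 7.1e-06, and adjusted p = 0.57 with an estimated correlation). C4a and C4b, complement component genes, rose 1.81-fold (adjusted p = 0.00424) and 1.61-fold (adjusted p = 0.0243) among 22 inflammatory and complement genes, whose median was 0.19 (camera adjusted p = 0.0215, and adjusted p = 0.64 with an estimated correlation). Of 27 interferon and antigen presentation genes 2 rose, Rsad2, an antiviral gene (1.83-fold), and Isg15, named after its values were seen (median 0.20, camera adjusted p = 0.0151, and adjusted p = 0.77 with an estimated correlation).

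Of 33 heat shock proteins and chaperones, Hspb2, a small heat shock protein of muscle, rose 1.28-fold (adjusted p = 0.0243) and Calr, the endoplasmic reticulum chaperone calreticulin, fell 1.34-fold (adjusted p = 0.0247). In this list 26 members were higher in old mice, with a median of 0.13 (camera adjusted p = 0.00893, and adjusted p = 0.57 with an estimated correlation). None of the 17 immediate early genes, the 25 fasting and PPAR target genes or the 3 lymphocyte markers passed singly. Their medians were 0.24, -0.22 and 0.67, and the camera adjusted p-values were 0.0218, 0.0144 and 0.037, against adjusted p-values of 0.71, 0.64 and 0.51 with an estimated correlation. Single members of other lists passed, namely Map1lc3a, an autophagosome protein (1.48-fold higher, while a second probe had a log2 difference of 0.07, p = 0.618), Cavin4, a caveolar protein of muscle (1.24-fold higher), Foxo4, a forkhead transcription factor (1.40-fold lower), and Heyl, a Notch target (1.53-fold lower). With each array scaled to its 75th percentile in place of quantile normalization, 67 genes rose and 74 fell. The mitochondrial lists are given with the other mitochondrial genes, and the remaining lists did not pass camera with age. Their medians were 0.30 for slow fibre genes, -0.04 for fast fibre genes, 0.09 for autophagy and lysosome, 0.05 for proteasome subunits, 0.01 for atrophy genes, -0.04 for glycolysis, -0.06 for lipid synthesis, -0.01 for clock genes, 0.02 for DNA repair and -0.01 for antioxidant enzymes. Among markers of cell types they were 0.30 for adipocytes, 0.16 for macrophages, -0.15 for endothelium, -0.54 for tendon, -0.08 for nerve, 0.49 for erythroid cells and 0.08 for satellite cells. With the chip as a block 281 genes passed. Within the 4 chips all 184 genes had the direction found across chips, but they were chosen on these same arrays. Over all genes, unselected but still on those arrays, the differences within a chip correlated with those across chips at 0.652 to 0.788. List medians within chips ran from 0.26 to 0.71 for the denervation genes, from -0.51 to -0.03 for the matrix genes and from -0.59 to 0.09 for the fibroblast markers, which were lower on 3 of the 4 chips, and the other 7 lists that passed had the direction found across chips on all 4. The count fell to 79, 32, 74 or 79 without young mouse 1, 2, 3 or 4, and to 94 or 68 without old ad libitum mouse 2 or 5, while array weights gave 482. Without old ad libitum mouse 1 the median of the interferon list was 0.00 (camera adjusted p = 0.535), and without young mouse 5 its adjusted p was 0.0691. The inflammatory list lost its call without old ad libitum mouse 3 or 6, the immediate early genes without young mouse 6 or old ad libitum mouse 6 (median 0.15 without the latter), the fasting list without young mouse 5, and the lymphocyte markers without any of 7 mice. Of 35 named genes changed with age, 8 passed without each mouse in turn. These were Cpne2, Slc23a3, Myh8, Spock2, Col4a4, Cpeb1, Chrnb1 and C4a, while Sln did not.

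Under caloric restriction, 5 of 24 lipid synthesis genes were higher and 4 of 22 inflammatory and complement genes lower than in old ad libitum mice past the threshold. Elovl6, which elongates palmitate, was 6.10-fold higher in restricted mice (log2 difference 2.61 ± 0.44 SE, adjusted p = 0.00888), with all 5 restricted mice above all 6 old ad libitum mice. Scd1, the stearoyl-CoA desaturase, was 2.30-fold higher (adjusted p = 0.0331) and Acly, the ATP citrate lyase, 2.44-fold higher (adjusted p = 0.0478). C4a fell 2.13-fold (adjusted p = 0.000705) and Mpeg1, a macrophage gene, fell 2.33-fold (adjusted p = 0.00347), each with all 5 restricted mice below all 6 old ad libitum mice. In total 284 genes passed, of which 82 rose and 202 fell, and 33 changed more than 2-fold. Other large rises were those of Acot1, an acyl-CoA thioesterase (3.25-fold), Dkk3 (3.12-fold), Cyp2e1, a cytochrome P450 (2.76-fold), Kcnf1, a potassium channel subunit (2.62-fold), Htra4 (2.44-fold), Cntnap2 (2.42-fold) and Lonrf3 (2.20-fold). Timp1, an inhibitor of matrix metalloproteinases, fell 3.51-fold (adjusted p = 0.0176), and Mmp3, a matrix metalloproteinase, fell 2.57-fold (adjusted p = 0.0145). Hp, encoding haptoglobin, fell 2.51-fold (adjusted p = 0.033) and Cdkn1a, the cell cycle inhibitor p21, fell 2.47-fold (adjusted p = 0.0288). Several genes were not detected on any array of restricted mice. Of these Kif5c, a kinesin heavy chain, was at least 1.76-fold higher in old ad libitum mice (adjusted p = 0.00051). The bounds for the chemokine gene Ccl5, for Mmp12, a macrophage elastase, for the chemokine gene Ccl7 and for Csprs were at least 1.37-fold, 1.26-fold, 1.25-fold and 1.17-fold.

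**Figure D1:**
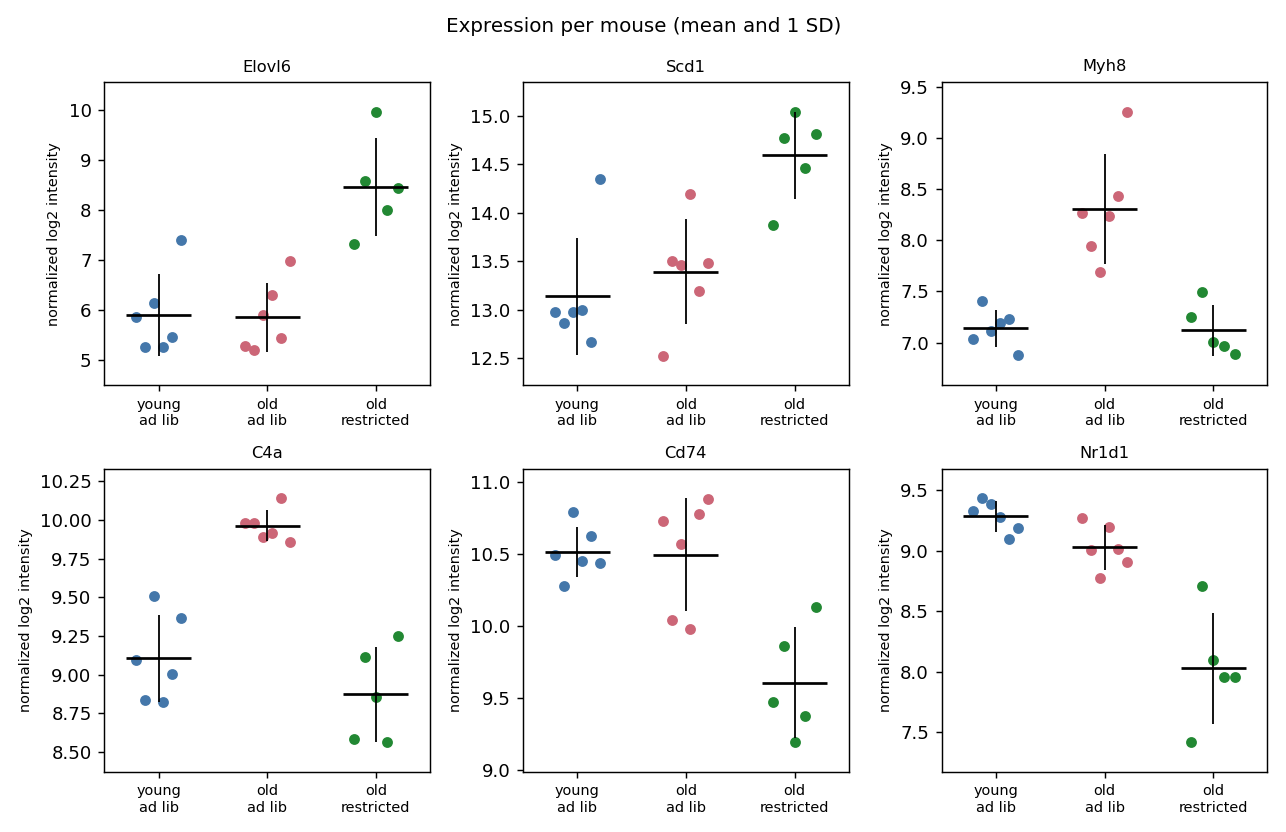
Normalized log2 values of 6 genes in each mouse, with points for mice, horizontal bars for group means and vertical lines for 1 SD, in young ad libitum (n = 6), old ad libitum (n = 6) and old caloric restricted (n = 5) mice. All 5 restricted mice lie above all 6 old ad libitum mice for Elovl6 and below them for C4a and Nr1d1, and all 6 old ad libitum mice lie above all 6 young mice for Myh8 and C4a.

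Of the 24 measured lipid synthesis genes, 5 rose under restriction, none fell and 22 were higher, with a median log2 difference of 0.25 (camera adjusted p = 1.6e-06, and adjusted p = 0.51 with an estimated correlation). Without restricted mouse 4 the median was 0.39. Besides Elovl6, Scd1 and Acly these were Fasn, the fatty acid synthase (1.63-fold, adjusted p = 0.0431), and Insig1, a regulator of sterol sensing (1.61-fold, adjusted p = 0.0309). The adipocyte markers, which share no member with this list, had a median of -0.09 in the same comparison, and none of the 14 passed. Of 25 fasting and PPAR target genes 3 rose, Acot1, Lpin1, a phosphatidate phosphatase (1.23-fold), and Igf1r, the receptor of insulin-like growth factor (1.31-fold), with a median of 0.21 (camera adjusted p = 0.00307, and adjusted p = 0.57 with an estimated correlation), or of 0.12 without restricted mouse 4. None of the 15 slow fibre genes passed, with a median of 0.49 (camera adjusted p = 0.0169, and adjusted p = 0.76 with an estimated correlation). This list varied widely within groups, with a mean per mouse of 0.62 ± 0.98 (SD, n = 5) in restricted and -0.02 ± 0.92 (SD, n = 6) in old ad libitum mice. It lost its call without old ad libitum mouse 4 or 5 (medians 0.28 and 0.27) or without restricted mouse 3, its median was 0.79 without old ad libitum mouse 2 or restricted mouse 5, and within chips its median ran from -0.87 to 1.36, positive on 2 of the 4 chips.

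All 27 interferon and antigen presentation genes were lower in restricted mice, with a median of -0.40, and 4 fell over all genes tested and 11 when adjusted over the list alone (camera adjusted p = 3.4e-07, and adjusted p = 0.58 with an estimated correlation). Old ad libitum mouse 1 had a mean of 0.91 over this list, against 0.18 in the next highest mouse of its group, and without it the median was -0.23 (camera adjusted p = 2.7e-05). The 4 genes were Cd74, the invariant chain of MHC class II (1.85-fold, adjusted p = 0.0176), the MHC class II genes H2-Ab1 (1.79-fold) and H2-Eb1 (1.81-fold), and Ifi27l2a, named after its values were seen. Of 22 inflammatory and complement genes 4 fell, C4a, C4b (2.13-fold, adjusted p = 0.00219), Ccl5 and Ccl7, with a median of -0.53 (camera adjusted p = 4.5e-05, and adjusted p = 0.51 with an estimated correlation). Markers of immune cells moved with these lists, but the lists share members. Ccl5 is in both the inflammatory and the lymphocyte list, and C1qa and C1qb are in both the inflammatory and the macrophage list. Among 17 macrophage and myeloid markers, Lgals3, encoding galectin-3 (1.77-fold), and Tyrobp, a myeloid adaptor (1.65-fold), fell, with a median of -0.36 (camera adjusted p = 0.00435, and adjusted p = 0.71 with an estimated correlation). Only 3 lymphocyte markers were measured, of which Cd52 fell 2.31-fold (adjusted p = 0.0145) and Ccl5 also fell (camera adjusted p = 0.00536, and adjusted p = 0.51 with an estimated correlation). Nr1d1, a repressor of the circadian clock, fell from a mean log2 value of 9.03 ± 0.18 (SD, n = 6) in old ad libitum to 8.03 ± 0.46 (SD, n = 5) in restricted mice (adjusted p = 0.00506). Clock, an activator of it, fell 1.29-fold (adjusted p = 0.0149), while a second probe had a log2 difference of -0.11 (p = 0.370). The 14 clock genes had no common shift (median -0.01, camera adjusted p = 0.848). In the matrix list Timp1 and the collagen prolyl hydroxylases P4ha1 (1.44-fold) and P4ha2 (1.37-fold) fell, with no shift of the 33 genes together (median -0.04, camera adjusted p = 0.385). Of the denervation genes Myh8 (2.27-fold) and Cdkn1a fell, with a median of -0.14 (camera adjusted p = 0.0573). Other probes of Myh8 had log2 differences of -0.77 and -0.30, against -1.18 for the probe used. Fbp2, the muscle fructose bisphosphatase, rose 1.92-fold (adjusted p = 0.0263), Hspa1l fell 1.27-fold, Cavin4 fell 1.21-fold and Egfl8 fell 1.34-fold. Medians of the remaining lists under restriction were 0.01 for glycolysis, 0.02 for fast fibre genes, -0.04 for autophagy and lysosome, 0.06 for proteasome subunits, -0.04 for atrophy genes, -0.11 for DNA repair, -0.10 for heat shock proteins, 0.04 for immediate early genes and 0.03 for antioxidant enzymes. Among markers of cell types they were -0.02 for endothelium, 0.14 for fibroblasts, -0.03 for tendon, 0.07 for nerve, -0.07 for erythroid cells and 0.02 for satellite cells. None of these lists passed camera.

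With the chip as a block 372 genes passed. Within the 4 chips between 95.1% and 100% of the 284 genes, which were chosen on these same arrays, had the direction found across chips. Over all genes the correlation with the differences across chips was 0.562 to 0.779, which is raised because those differences include the same arrays. The lipid synthesis list had medians from 0.14 to 0.52 within chips and the interferon list from -0.58 to -0.11, and the lymphocyte markers were lower on all 4 chips. The inflammatory list (-0.83 to 0.06) and the macrophage list (-0.74 to 0.03) were lower on 3 of the 4 chips, and the fasting list (-0.04 to 0.35) was higher on 3 of the 4. The count was 180, 120 or 145 without old ad libitum mouse 2, 5 or 6, and 66, 67 or 106 without restricted mouse 1, 3 or 4, while it was 502 without restricted mouse 5. Fitted on the mice of these 2 groups alone, 24 genes passed, all of which were among the 284. Of these 4 rose and 20 fell, so the 5 lipid synthesis genes did not all pass there. Of 47 named genes changed under restriction, 11 passed without each mouse in turn. These were Elovl6, Kif5c, Csprs, Mpeg1, Nr1d1, C4a, C4b, Mmp3, Cd52, Clock and Myh8, while Scd1, Acly and Fasn each lost their call without at least 1 mouse.

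**Figure D2:**
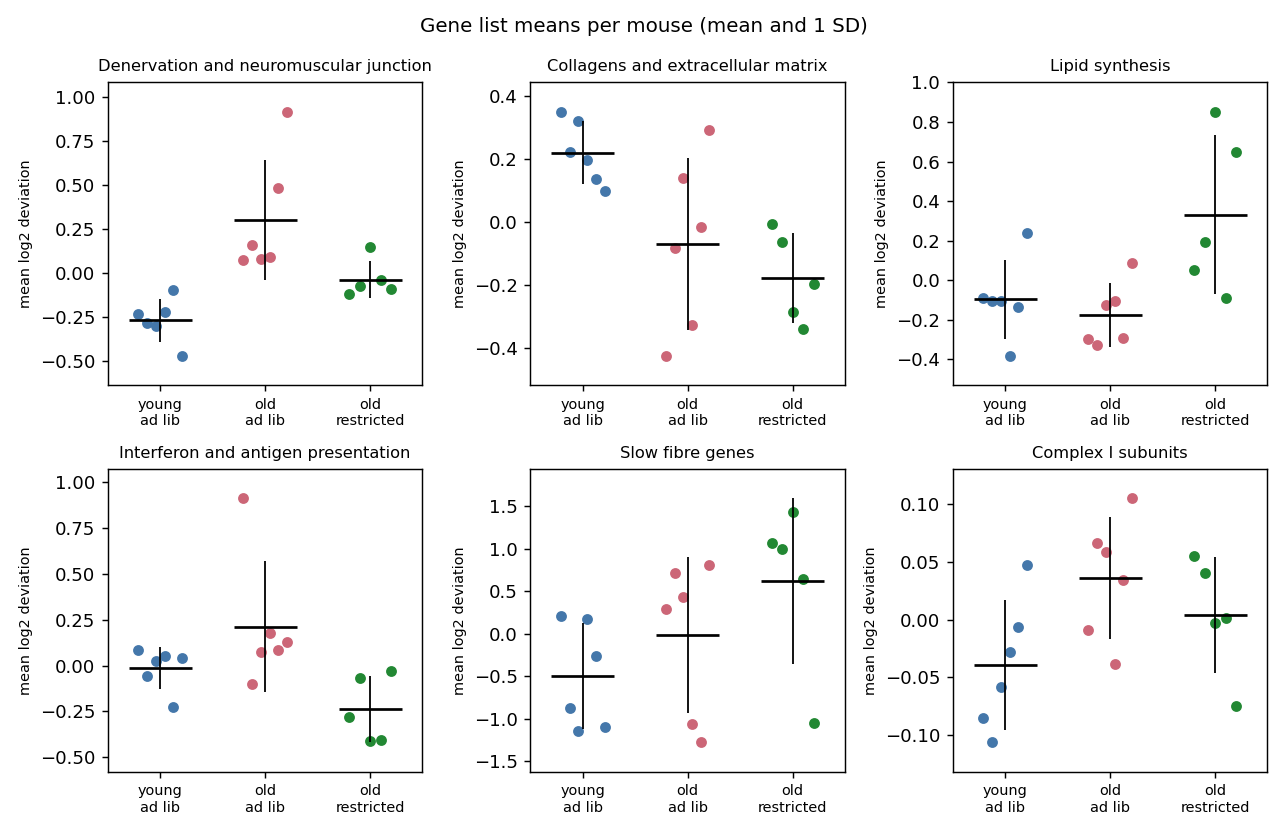
Mean of each mouse's deviations from the mean of all mice, in log2 units, over the measured members of 6 gene lists, with points for mice, horizontal bars for group means and vertical lines for 1 SD (n = 6, 6 and 5 mice). The denervation list averages 0.30 in old ad libitum and -0.27 in young mice, and the slow fibre list spreads over more than 2 log2 units within the restricted group.

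Restricted mice differed from young mice in both age and diet. The slow myosin gene Myh7 was 3.47-fold higher (log2 difference 1.80 ± 0.50 SE, adjusted p = 0.049) and Myh6, a myosin heavy chain gene of heart, 3.25-fold higher in restricted mice. Kcnf1 was 4.47-fold higher (adjusted p = 0.0018), with all 5 restricted mice above all 6 young mice, Elovl6 5.89-fold higher (adjusted p = 0.00558) and Acsm3, an acyl-CoA synthetase, 3.04-fold higher. Here 421 genes passed, of which 181 rose and 240 fell, and 26 changed more than 2-fold. Of 33 collagen and matrix genes 8 fell, with a median of -0.43 (camera adjusted p = 1.1e-08, and adjusted p = 0.51 with an estimated correlation), among them P4ha2 (1.58-fold, adjusted p = 0.00558) and P4ha1 (1.49-fold). Another 4 lists were higher, namely 15 slow fibre genes (median 0.97, camera adjusted p = 5.5e-05), lipid synthesis (median 0.22, camera adjusted p = 0.00398), immediate early genes (median 0.37, camera adjusted p = 0.00496) and the denervation genes (median 0.17, camera adjusted p = 0.0215). For each of these 4 the adjusted p was 0.64 with an estimated correlation. Proteasome subunits were higher by a median of 0.10 (camera adjusted p = 0.0347, and adjusted p = 0.57 with an estimated correlation). Endothelial markers (median -0.17), fibroblast markers (median -0.25) and interferon genes (median -0.13) were lower, with camera adjusted p-values of 0.0192, 0.0394 and 0.027, against adjusted p-values of 0.64, 0.77 and 0.81 with an estimated correlation. Nr1d1 fell 2.39-fold (adjusted p = 0.000781) and Clock 1.36-fold (adjusted p = 0.00359), as both did against old ad libitum mice. The probes of Clock differ, however. A second probe fell with age (log2 difference -0.62, p = 2.6e-05, against -0.07 for the probe used) and had -0.11 under restriction (p = 0.370).

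The largest falls in this comparison included those of genes that liver expresses strongly. Mup2, a major urinary protein, was not detected in restricted mice and was at least 12.7-fold higher in young mice (adjusted p = 0.0444), Serpina1d and Serpina1b, which encode alpha-1 antitrypsin, fell 6.47-fold and 5.66-fold (adjusted p = 0.0138 for each). On arrays of restricted mice Serpina1d lay at 5.15 to 6.04, close to Mup2, which was not detected at up to 5.69. The fold of Serpina1d thus rests on values near background. Of other genes, Tph2, a tryptophan hydroxylase, was not detected in restricted mice and was at least 2.88-fold higher in young mice (adjusted p = 0.0136), and Ubd, a ubiquitin-like protein, fell 3.59-fold (adjusted p = 0.0243). Ubd was at 5.91 in restricted mouse 2 and at most 5.29 in the others of that group, so its fold also rests on values near background. The SD of Mup2 between young mice was 3.48, against 0.36 between restricted mice. High values were found in young mice 1, 2 and 3, at 13.62, 12.27 and 12.48, while young mice 4, 5 and 6 had 6.86, 6.61 and 6.09. Old ad libitum mice 5 and 6 had 9.08 and 9.18, the other 4 of that group 5.52 to 7.37 and restricted mice 4.78 to 5.69. Serpina1b was at 8.31 and 8.90 and Serpina1d at 7.20 and 7.58 in young mice 5 and 6, above all 5 restricted mice, while young mouse 4, at 6.88 and 5.59, was within their range. Without young mice 1, 2 and 3 the log2 differences of Mup2, Serpina1b and Serpina1d were -1.37 ± 0.71 SE, -1.28 ± 0.36 SE and -1.36 ± 0.38 SE, against -4.50 ± 1.23 SE, -2.50 ± 0.52 SE and -2.69 ± 0.56 SE with all mice, and none passed. As Mup2 was not detected in restricted mice, its differences and its SD of 0.36 there rest on values at background, and only the bound gives a fold. The repeated array of young mouse 2 gave 12.22 against 12.32 on another chip. Probes of C4a and C4b, and of the Serpina1 and Mup families, can bind transcripts of close copies, as can those of Amd2 and Csprs, so that these values belong to the families.

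**Figure D3:**
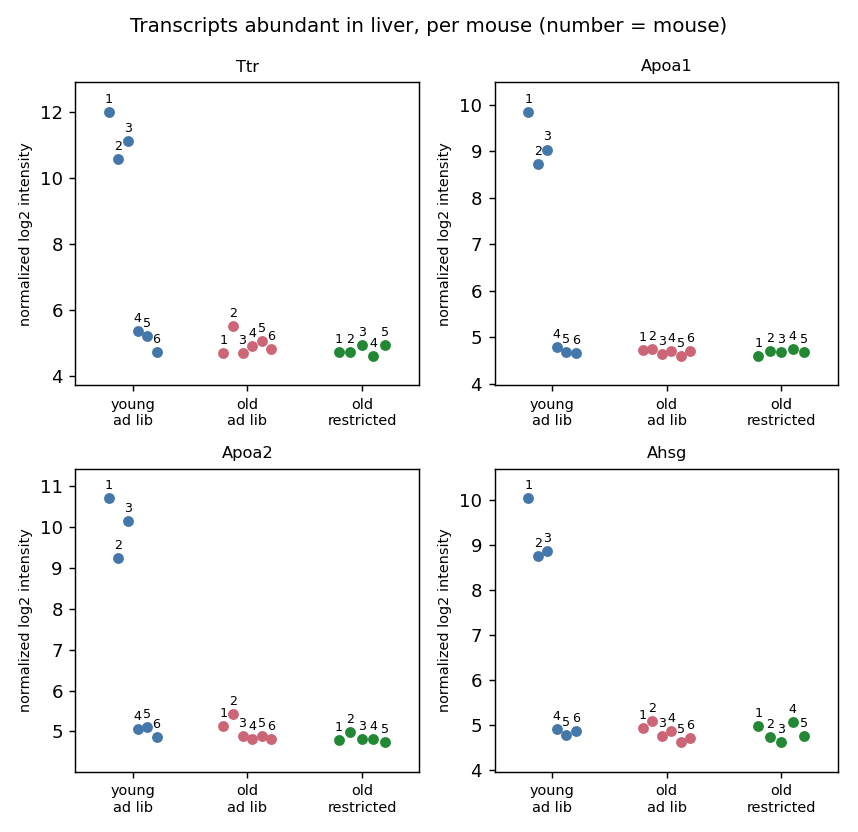
Normalized log2 values of 4 transcripts that liver expresses strongly (Ttr, Apoa1, Apoa2 and Ahsg), with 1 point per mouse, numbered within its group. Young mice 1, 2 and 3 stand apart for all 4 transcripts, with Ttr at 12.01, 10.59 and 11.14, while Ttr was detected on no array of the other mice.

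With the chip as a block 546 genes passed. Within the 4 chips between 99.3% and 100% of the 421 genes, chosen on these same arrays, had the direction found across chips. Over all genes the correlation with the differences across chips was 0.701 to 0.848, again raised because those differences include the same arrays. Of the 9 lists that passed, the interferon list was lower on 3 of the 4 chips (medians -0.22 to 0.02), and the others had the direction found across chips on all 4, with slow fibre medians from 0.26 to 1.90. With each array scaled to its 75th percentile 84 genes rose and 397 fell, and the median of all genes was then -0.07 against -0.01. The count was 170, 136, 176 or 194 without young mouse 1, 2, 3 or 4. It was 215, 204, 131 or 240 without restricted mouse 1, 2, 3 or 4, was 691 without restricted mouse 5, and was 1147 with array weights. Without young mice 1, 2 and 3, a choice made after their values were seen, 3 genes passed here and 1 with age. All 421 genes kept their direction, with a median size of 0.40 against 0.45 and a median SE of 0.13 against 0.11. They too were selected on data that include the mice kept, so this is no independent support. Lists that lost their call without a single mouse were lipid synthesis and endothelial markers (restricted mouse 5), denervation (young mouse 6, restricted mouse 3 or 5), proteasome (young mouse 4, restricted mouse 4 or 5), interferon (young mouse 1 or 6, restricted mouse 3 or 4) and fibroblast markers (young mouse 1, 3 or 6, restricted mouse 3, 4 or 5). Without restricted mouse 3 the lipid synthesis median was 0.14, without restricted mouse 4 the denervation median 0.25 and without restricted mouse 5 the interferon median -0.22. Myh7 lost its call without young mouse 1, 2 or 3, among others.

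Of the lists of mitochondrial genes, the mitochondrial ribosome passed camera with age, and none passed under restriction or for restricted against young mice. Of the 34 subunits of complex I none passed with age or under restriction, with medians of 0.05 (camera adjusted p = 0.0986) and -0.03 (camera adjusted p = 0.78). No member of complexes II and III (12 measured) or of complex IV (12 measured) passed, with age medians of 0.06 and 0.07 and restriction medians of -0.02 and -0.02. Of 15 ATP synthase subunits Atp5e rose with age (1.34-fold, adjusted p = 0.0417), with list medians of 0.10 with age and 0.00 under restriction (camera adjusted p = 0.0986 and 0.974). The tricarboxylic acid cycle (20 measured) and fatty acid oxidation (24 measured) had medians of 0.03 and 0.00 with age and -0.07 and -0.03 under restriction, with no member past the threshold in either comparison. Of 71 mitochondrial ribosome genes none passed singly, but 55 were higher with age (median 0.08, camera adjusted p = 0.0112, and adjusted p = 0.57 with an estimated correlation) and 51 lower under restriction (median -0.07, camera adjusted p = 0.0622).

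Of 26 regulators of mitochondrial biogenesis, Nrip1, a corepressor of oxidative metabolism genes, rose under restriction (1.62-fold, adjusted p = 0.022), with list medians of 0.04 with age and -0.06 under restriction (camera adjusted p = 0.974 and 0.993). Ppargc1a, encoding the coactivator PGC-1 alpha, had a log2 difference of -0.18 ± 0.12 SE with age (adjusted p = 0.438) and 0.43 ± 0.13 SE under restriction (adjusted p = 0.0719), so that neither passed. Sirt3, a mitochondrial deacetylase, had a difference of -0.31 ± 0.09 SE under restriction (adjusted p = 0.0631), and Sirt1 had 0.28 ± 0.14 SE. For Ppargc1b, Nrf1, Tfam, Esrra and Cs, the citrate synthase often used as a marker of mitochondrial content, the differences under restriction were -0.02, -0.04, 0.11, -0.21 and 0.04, with SEs of 0.16, 0.08, 0.07, 0.11 and 0.10. Ppara was not among the genes tested. Of 35 antioxidant genes Gpx4, a glutathione peroxidase, rose with age (1.27-fold, adjusted p = 0.0215), and under restriction Gclm, of glutathione synthesis, rose 1.28-fold (adjusted p = 0.0288), as did Gpx8, while Mt2 fell, the last 2 named after their values were seen. Sod2, Cat and Gpx1 differed with age by -0.01 ± 0.08 SE, -0.39 ± 0.16 SE and 0.38 ± 0.13 SE and under restriction by -0.14 ± 0.08 SE, 0.36 ± 0.17 SE and -0.23 ± 0.13 SE, with none past the threshold. Ucp3 and Pdk4 differed under restriction by 0.72 ± 0.36 SE and 0.92 ± 0.42 SE (adjusted p = 0.287 and 0.236). Of the fusion, fission and mitophagy genes (18 measured) none passed with age or under restriction, with medians of -0.03 and -0.01. For restricted against young mice the medians were 0.05 for complex I, 0.03 for complexes II and III, 0.06 for complex IV, 0.07 for ATP synthase, 0.01 for the tricarboxylic acid cycle, -0.03 for fatty acid oxidation and -0.03 for biogenesis regulators. Against young mice, restricted mice had higher Slc27a1, a fatty acid transporter (log2 difference 0.56), and Mief2, a fission factor (0.37).

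Of the 184 genes changed with age, 92.9% had a restriction difference of opposite sign. These comparisons share the old ad libitum mice, and 100 simulated sets of unchanged groups gave a median of 90.8% (range 57.1% to 100%) over as many genes. Across all genes, which are not independent replicates, the covariance of the age and the restriction difference was -0.0211 against a simulated median of -0.00975. The range of the simulated covariance was not kept, so this difference cannot be judged against its spread. The correlation was -0.40 against a simulated median of -0.48 (range -0.82 to -0.006). When the old ad libitum mice were split into groups of 3, with a different group used for each difference, the share had a median of 70.9% over the 20 splits (range 52.2% to 84.2%) and the correlation a median of -0.12, negative in 19 of the 20. There were 28 genes that rose with age and fell under restriction, against 2.71 expected from independent lists, and 7 that fell and rose, against 0.587 expected. No gene changed in the same direction in both, against 1.10 and 1.45 expected. Because the old ad libitum mice enter both comparisons, opposite calls are favoured and like calls disfavoured by chance, so these expected counts are not the values for unchanged groups, and no overlap was simulated with shared mice. Among the 28 were C4a, C4b, Myh8, Uchl1, Kif5c, Cpne2, Csprs and Cavin4, and among the 7 were Htra4, Dlk1 and Amd2.

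**Figure D4:**
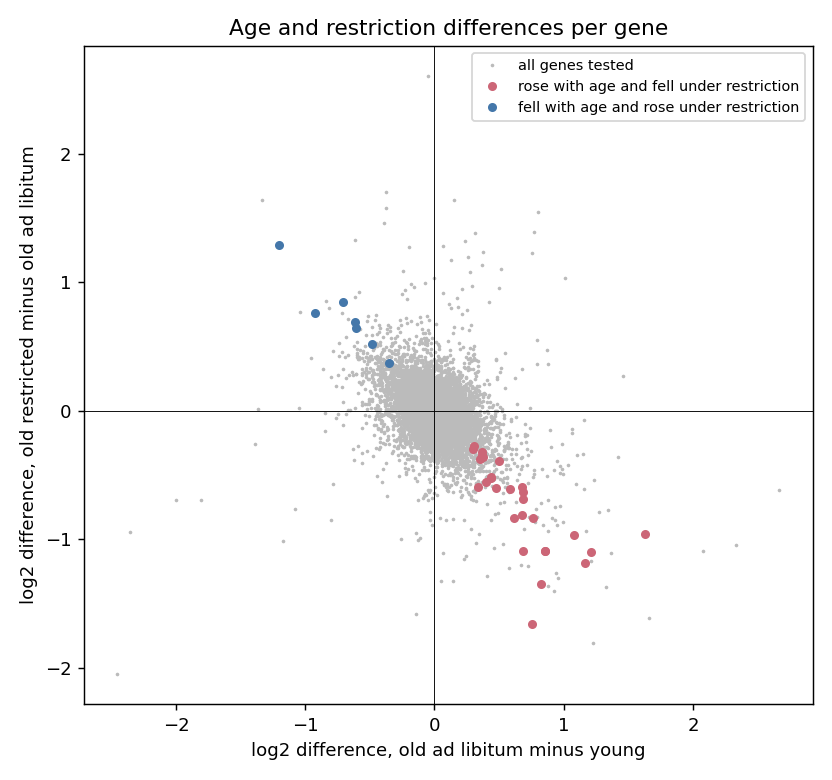
Log2 difference under restriction (old caloric restricted minus old ad libitum) against log2 difference with age (old ad libitum minus young) for the 8943 genes tested, with the 28 genes that rose with age and fell under restriction and the 7 that fell and rose in colour. Both axes share the old ad libitum mice, which tilts the cloud (correlation -0.40 across genes, simulated median -0.48).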

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

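The tests of slow fibres, of fat, of chips and of liver transcripts below were chosen after the results were seen, and the tests of nerve markers and of other splits of the mice before. Of 333 sets of values of a gene in a group, 23 had a mouse far from the others, and of 105 sets for a gene list 6 had, while chance gives about 1 in 20. The value given for each is the gap to the nearest other mouse as a share of the range of the group.

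In young mice, Abi3bp (0.740) was highest and Atp5e (0.672) lowest in mouse 3, Calr (0.701), Icam1 (0.812) and Ttc9 (0.627) were highest and Chrnb1 (0.755) lowest in mouse 1, and Uchl1 (0.732) was lowest in mouse 2. Bcl2a1d (0.644), Hp (0.653), Mmp12 (0.721), Tph2 (0.720) and Ubd (0.743) were lowest in mouse 4. Hspa1l (0.744) and the fasting list (0.632) were highest in mouse 5, and Scd1 (0.798) and Slc1a3 (0.734) in mouse 6. In old ad libitum mice, Auts2 (0.785), Lonrf3 (0.648) and the interferon list (0.723) were highest in mouse 1, Spock2 (0.728) and the endothelial markers (0.637) in mouse 4, and the satellite cell markers (0.754) in mouse 6. In restricted mice, Cyp2e1 (0.849) was lowest in mouse 1, Cd52 (0.712), Mpeg1 (0.717) and Ubd (0.804) were highest in mouse 2, the denervation list (0.713) in mouse 3 and the atrophy list (0.763) in mouse 4, in which Ddit3 (0.775) was lowest.

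Among genes outside the comparisons, 43 were detected on all 4 arrays of young mice 1, 2 and 3 and on no other array, 11 of them on a list of liver genes. The other 32 are not a set without liver genes. They included Mup3, Mup5, Mup20, Mup21, Serpina1a, Serpina1c and Serpina1e, of the Mup and Serpina1 families, and the apolipoprotein genes Apob, Apoc4 and Apof. Also among them were Azgp1, Bhmt, Crp, Cyp2a5, Cyp2d9, Cyp4a12a, Cyp8b1, F2, Hamp, Itih1, Itih2 and Itih3. The rest were Mat1a, Mettl7b, Rdh7, Slc27a2, Slco1b2, Ugt2b36, Uox, Uroc1, Nktr and Rab5b. Of 22 liver genes with a probe, 12 were detected on at least 3 arrays of young mice and on no array of old mice, against 56 of 19035 other genes (Fisher's exact test, two-sided, p = 9.6e-25). This test takes genes as independent, but they were read on the same arrays, so its p-value measures no spread between mice. The 56 other genes include the 32 above. With the chip as a block the median over Mup2, Serpina1b and Serpina1d was -2.64, against -2.69 without it, which argues against differences between chips. The median over the 22 liver genes was -0.99 with an SD of 1.05, which decided nothing, and Alb, Fgb, Fabp1 and Tat were detected on no array. Most of the 22 were detected on no array of restricted mice, so this median rests on values at background there. Young mice 4, 5 and 6 had Ttr at 5.37, 5.20 and 4.73 and Apoa1 at 4.79, 4.70 and 4.67, undetected as in old mice, which argues against age or diet alone for these 2, but without young mice 1, 2 and 3 Serpina1b and Serpina1d still had differences of -1.28 ± 0.36 SE and -1.36 ± 0.38 SE between restricted and young mice, so liver RNA in those 3 samples may be the source of a part, as a hypothesis, while age and diet stay open for the rest.

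The denervation genes were higher in old ad libitum mice by 0.57 ± 0.13 SE in the mean of the list. With the nerve and Schwann cell score as a covariate, which shares no member, the difference was 0.59 ± 0.13 SE. Over the members not also in the slow fibre list it was 0.51 ± 0.12 SE with the slow fibre score as a covariate, against 0.52 ± 0.11 SE without it. Both stayed above a bound of 50% of the uncorrected difference by more than 2 SE, which argues against slow fibres or nerve tissue as the whole source. An effect of age may be the source, as a hypothesis, and mice 5 and 6 carried the highest values.

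The lipid synthesis genes were higher in restricted mice by 0.51 ± 0.16 SE in the mean of the list. With the adipocyte score as a covariate the difference was 0.53 ± 0.15 SE, and with the slow fibre score it was 0.54 ± 0.17 SE. Neither stayed above 50% of the difference, which is 0.25, by more than 2 SE, as the values less 2 SE were 0.22 and 0.20. Neither covariate lowered the difference, and the adipocyte markers had a median of -0.09, but the SE leaves open that fat tissue or fibre type may account for a part, as it leaves an effect of diet open.

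For each comparison 100 splits of the mice were drawn, the real one included. They argue against chance for the number of genes but do not exclude it. With age the real split gave 184 genes and the highest other 1, and 1 of the 100 splits gave as many. Under restriction the real split gave 284 and the highest other 230, with 1 as large, and for restricted against young 421 and 428, with 2 as large. For the number of gene lists, adjusted within each comparison, the splits do not argue against chance. With age 13 splits gave as many as the real 12 lists (highest other 19), under restriction 56 gave as many as 7 (highest other 15) and for restricted against young 19 gave as many as 9 (highest other 14).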

How the results depend on the processing

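The covariates and the mice left out in pairs or more were chosen after the data were seen. No value of a list or named gene past its threshold changed direction. Of 442 values of the 26 list shifts without 1 mouse, 407 stayed past the threshold. Under 14 other settings fixed beforehand that kept the preset correlation, 356 of 364 did. Of 1989 values of named genes 1441 did without 1 mouse, and 1374 of 1619 did under the other settings fixed beforehand. Under the settings chosen after the data were seen, fewer stayed past the threshold, with 85 of 104 list values and 281 of 468 values of named genes. Without 1 mouse the count with age ran from 32 to 262, under restriction from 66 to 502 and for restricted against young from 131 to 691, the lists from 21 to 35 and the share of age genes with opposite sign from 85.3% to 96.9%. The replicate block, by number in the labels, gave 107, 88 and 244 genes, but same-numbered mice did not deviate together (median r = -0.04, 5 of 16 pairs over 0.1, and 1 of 17 mice matched its number best), so the numbers do not pair the mice. Without a detection filter 95 genes passed with age, 273 for restricted against young and 41 lists. With age 281 passed with the chip as a block and 284 without it on 24 arrays, 510 of all kept probes, 286 with the mean of a gene's probes, and 482 with array weights. For restricted against young 645 of all kept probes passed, 1147 with array weights and 244 with the slow fibre score as a covariate. Fits on the 2 groups alone gave 24 genes under restriction. Array weights gave a share of opposite sign of 83.2%, and splitting the old ad libitum mice gave 70.9%. With an estimated correlation 0 lists passed, and with fry 7, of which 5 were among the 26. With age fry passed denervation (adjusted p = 0.010), the mitochondrial ribosome (0.026) and, outside the 26, autophagy (0.026) and fast fibre genes (0.041). Under restriction it passed the inflammatory (0.025) and lymphocyte (0.010) lists. The matrix list with age and lipid synthesis under restriction each had a fry adjusted p of 0.058, and interferon genes had 0.37 with age and 0.069 under restriction. Without old ad libitum mice 5 and 6, 108 genes passed with age and 90 under restriction, and without young mice 1, 2 and 3, which leaves 3 young mice, 1 passed with age, 66 under restriction and 3 for restricted against young. For settings other than more probes tested, the cause was not tested. The detection filter leaves out probes detected on fewer than 5 arrays. It keeps genes at background throughout a group, such as Mup2 and Kif5c in restricted mice.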

Other observations

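Further genes that rose with age and fell under restriction, named after their values were seen, included Mthfd2, a mitochondrial enzyme of folate metabolism, which had a log2 difference of 0.86 ± 0.13 SE with age (adjusted p = 0.00359) and -1.09 ± 0.13 SE under restriction (adjusted p = 0.000604). Trib3, a stress-response pseudokinase, had 0.68 ± 0.14 SE and -0.60 ± 0.14 SE. The transcription factor genes Atf4 and Ddit3 had 0.07 ± 0.10 SE and 0.35 ± 0.19 SE with age, and neither passed. Casp4, an inflammatory caspase, had 0.68 ± 0.14 SE with age and -0.69 ± 0.15 SE under restriction, Icam1, an adhesion molecule, 0.40 ± 0.09 SE and -0.55 ± 0.10 SE, Cxcl16, a chemokine gene, 0.69 ± 0.14 SE and -0.63 ± 0.14 SE, and Bcl2a1d 0.62 ± 0.13 SE and -0.83 ± 0.13 SE. Trib3, Casp4, Icam1, Cxcl16 and Bcl2a1d all passed in both comparisons, which share the old ad libitum mice, so opposite signs arise in part by chance.

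Other clock genes, also named after their values were seen, did not pass under restriction beside Nr1d1 and Clock. Per2 had a log2 difference of 0.83 ± 0.33 SE (adjusted p = 0.17), Dbp -0.62 ± 0.34 SE (adjusted p = 0.328), Arntl -0.25 ± 0.35 SE (adjusted p = 0.743) and Per1 0.10 ± 0.51 SE (adjusted p = 0.943).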
